A study of Homo sapiens with 6 samples.

How the data were processed

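Total RNA from HCT-116 cells, an established human colorectal carcinoma line, was extracted with Trizol, labelled with biotin by in vitro transcription and hybridised to Affymetrix PrimeView arrays, per the labels' protocols and the probe table. There were 6 arrays: 3 from cells given the vehicle DMSO and 3 from cells given the compound coded AAPK. The treatment field, which reads the same for all 6 samples, gives 10 µM and 48 h; the 10 µM is taken here as the dose of AAPK. Groups and replicate numbers were taken from the sample titles.

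The deposited table holds log2 signal values for 49395 probe sets, with no missing value. The scale is not stated, and log2 was read from the values, which run from 2.83 to 14.25 on the 6 arrays and so lie within the range of a 16-bit scanner as log2 and far above it as natural logs. The quartiles of the arrays are nearly equal, so the authors' values had been normalised between arrays before deposit. The background correction, the normalisation and the way probes were summarised into probe sets are not given in the sources used here. A normalisation that equalises the arrays removes any change shared by most genes, so every change below is relative to the bulk of the genes on the array.

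Probe sets were named from the platform's gene table. Of the 49395 probe sets, 102 were Affymetrix controls, 44988 named 1 gene symbol, 1832 named several and 2473 named none. Of the 44988 single-symbol probe sets, 44961 had an Entrez identifier in the RefSeq gene table of assembly GRCh38.p14, and 0 symbols needed an update. Probe sets that named several genes or none were left out of the gene fit. For each of the 18132 genes the probe set with the highest mean log2 signal over all 6 arrays was used, whatever its group; 11734 genes had more than 1 probe set, and where a named gene's probe sets differ in direction, this is given beside it. Coordinates are not printed.

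Differences between AAPK and DMSO were tested gene by gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided), with Benjamini-Hochberg adjustment over the 18132 genes and a threshold of adjusted p 0.05. Every fold change is AAPK minus DMSO on the log2 scale, with its moderated standard error. The labels do not say that the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. For arrays, precision is limited by their number, 3 per group.

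There were 29 gene lists, for pathways, complexes and markers of other cell types, with 915 entries, of which 854 were measured; 818 of 878 distinct genes were named by a single-symbol probe set, and the rest are not analysed here. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 29 lists. Beside it stand camera with an estimated correlation; fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes; and the percentile of the list's median among 10000 random lists matched on mean signal. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. By that rule AURKA and PLK1 are always named, followed by the 8 genes with the largest rise and the 8 with the largest fall among genes past the threshold, with no overlap between the groups and a mean signal above the median gene. From each list the 2 members with the largest change past the threshold are named, or 4 for the lists of kinase targets and partners, G2/M and mitosis, tubulins, p53 targets and apoptosis regulators. Genes named outside this rule are marked as chosen after their values were seen.

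The fit was tested on simulated arrays with the residual spread of the real ones, for the comparison of AAPK with DMSO over 18132 genes of which 200 were changed. It recovered 47.8% of genes changed by 0.25 on the log2 scale, 95.5% of those changed by 0.5 and 100% of those changed by 1, and 1.82% of its 165 calls were unchanged genes. The real arrays gave 2788 calls. With so many fewer changed genes the adjustment was stricter in the simulation, so it may understate the recovery of small changes. With no list changed, 0 of 29 lists were called. The noise was drawn independently for each gene, whereas on the real arrays the estimated correlation was 0.14 for the G2/M list. This simulation therefore cannot show how often camera calls unchanged lists whose genes vary together. For the kinase, tubulin, NRF2 and YAP/TAZ lists the estimated correlation was -0.01, -0.03, -0.01 and -0.01, below the preset 0.01. A higher correlation between genes therefore cannot account for the calls that these lists lost with an estimated correlation. What else differs between the 2 versions of camera was not examined.

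The alternatives were quantile normalisation, centring each array on its median, leaving out genes under the 25th percentile or under the median of signal, the mean of a gene's probe sets or the probe set with the largest spread, fitting all probe sets, an intensity trend with robust eBayes, array weights, a block for the replicate number, leaving out each array in turn, and an adjusted p of 0.01. The planned pseudocounts applied only to linear values and were not run. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.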

Results

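Gene expression was measured on 6 arrays of HCT-116 colorectal carcinoma cells, 3 from DMSO controls and 3 from cells given AAPK at 10 µM for 48 h. The series title describes the compound as an inhibitor of the mitotic kinases Aurora A and PLK-1, and the comparison asks how it changes gene expression. Median log2 signal was 6.49, 6.50 and 6.48 on the DMSO arrays and 6.47, 6.46 and 6.47 on the AAPK arrays. Pearson correlations over all probe sets were 0.9976 to 0.9983 within a group and 0.9942 to 0.9954 between groups. The first principal component, with 60.8% of the variance, separated AAPK from DMSO.

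Chaperone and mitotic genes led the rise and amino acid stress-response genes led the fall. HSPA1B, a stress-inducible HSP70, rose 3.85-fold (log2 change 1.94 ± 0.06 SE, n = 3 per group, limma adjusted p = 3.74e-08), and HSPA8, the constitutive HSC70, rose 2.44-fold; 7 of its 8 other probe sets had the same sign and the lowest was at -0.05. CKS2, a subunit that binds cyclin-dependent kinases, rose 2.01-fold. DDIT3, which encodes the stress transcription factor CHOP, was 4.71-fold lower (log2 change -2.23 ± 0.05, adjusted p = 1.88e-08), and TRIB3, a pseudokinase induced by the same stress pathway, was 3.18-fold lower. GADD45A, a growth-arrest and DNA-damage gene, fell by 1.49 on the log2 scale. MAT2A, which makes S-adenosylmethionine, fell by 1.41, with -2.12 on its probe set with the largest spread, while 1 of its 5 other probe sets rose by 0.59. CAMTA2, a transcription activator, fell by 1.52 on its brightest probe set and had 0.07 on the other, which did not pass; the mean of both was -0.73. RNF144B, a ubiquitin ligase, fell by 1.41, with -0.28 and -0.08 on its other probe sets and a mean of -0.59. HSPA1B, HSPA8 and CKS2 were the 3 genes at least 2-fold higher, against 20 at least 2-fold lower.

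**Figure D1:**
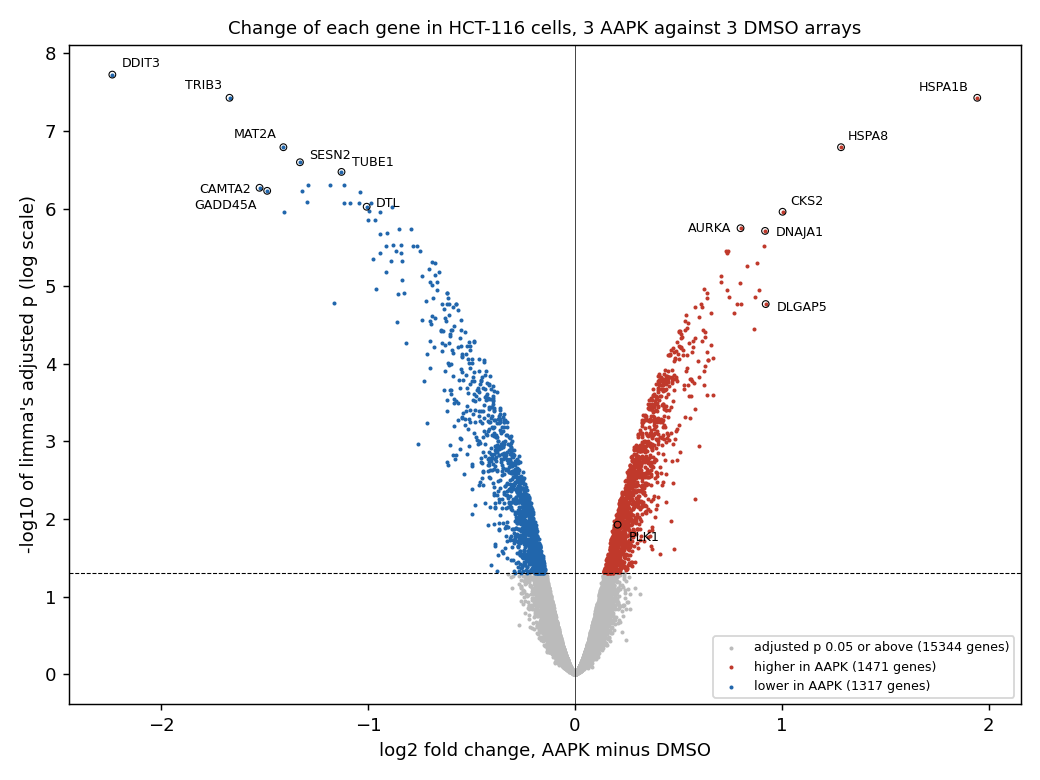
Change of each of the 18132 genes (horizontal axis, log2 fold change, AAPK minus DMSO) against -log10 of limma's adjusted p (vertical axis); red points are the 1471 genes higher in AAPK, blue the 1317 lower and grey the others, and the dashed line is adjusted p 0.05. DDIT3 at -2.23 and HSPA1B at 1.94 lie farthest out.

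In all, 2788 of 18132 genes passed the threshold, 1471 higher and 1317 lower in AAPK. Most changes were small: the median size among them was 0.26 on the log2 scale, and 159 reached 1.5-fold, 47 higher and 112 lower. The 3 AAPK arrays did not overlap the 3 DMSO arrays for 5793 genes, 31.9%, where chance gives 10%; all 2788 were among them.

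The transcript of AURKA, which encodes Aurora A, rose 1.74-fold, from 9.79 ± 0.02 (SD, n = 3) to 10.59 ± 0.02 log2 units (adjusted p = 1.79e-06). PLK1 rose less, 1.15-fold, from 7.37 ± 0.03 to 7.58 ± 0.04 (adjusted p = 0.0118), and its other 2 probe sets had log2 changes of 0.20 and 0.30. Of 17 measured kinase targets and partners, 7 rose and 1 fell, and adjusted over the list alone 8 rose and 2 fell. CDCA8 and BIRC5, partners of Aurora B in the chromosomal passenger complex, rose by 0.60 and 0.51 on the log2 scale (10 of the 11 other BIRC5 probe sets had the same sign, the lowest at -0.04), and AJUBA, a LIM protein that binds Aurora A, fell by 1.12. The list shifted upward with a median of 0.09 (camera adjusted p = 0.00214). It shares 6 genes with the G2/M list below, AURKA, PLK1 and BIRC5 among them, so the shifts of these lists are not independent. The call was lost with an estimated correlation (adjusted p = 0.114) and against random lists (adjusted p = 0.0503). The estimated correlation was -0.01, below the preset 0.01, so a higher correlation between genes does not explain the first loss. Both without DMSO replicate 3 and with genes under the median signal left out the list's median was 0.17.

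**Figure D2:**
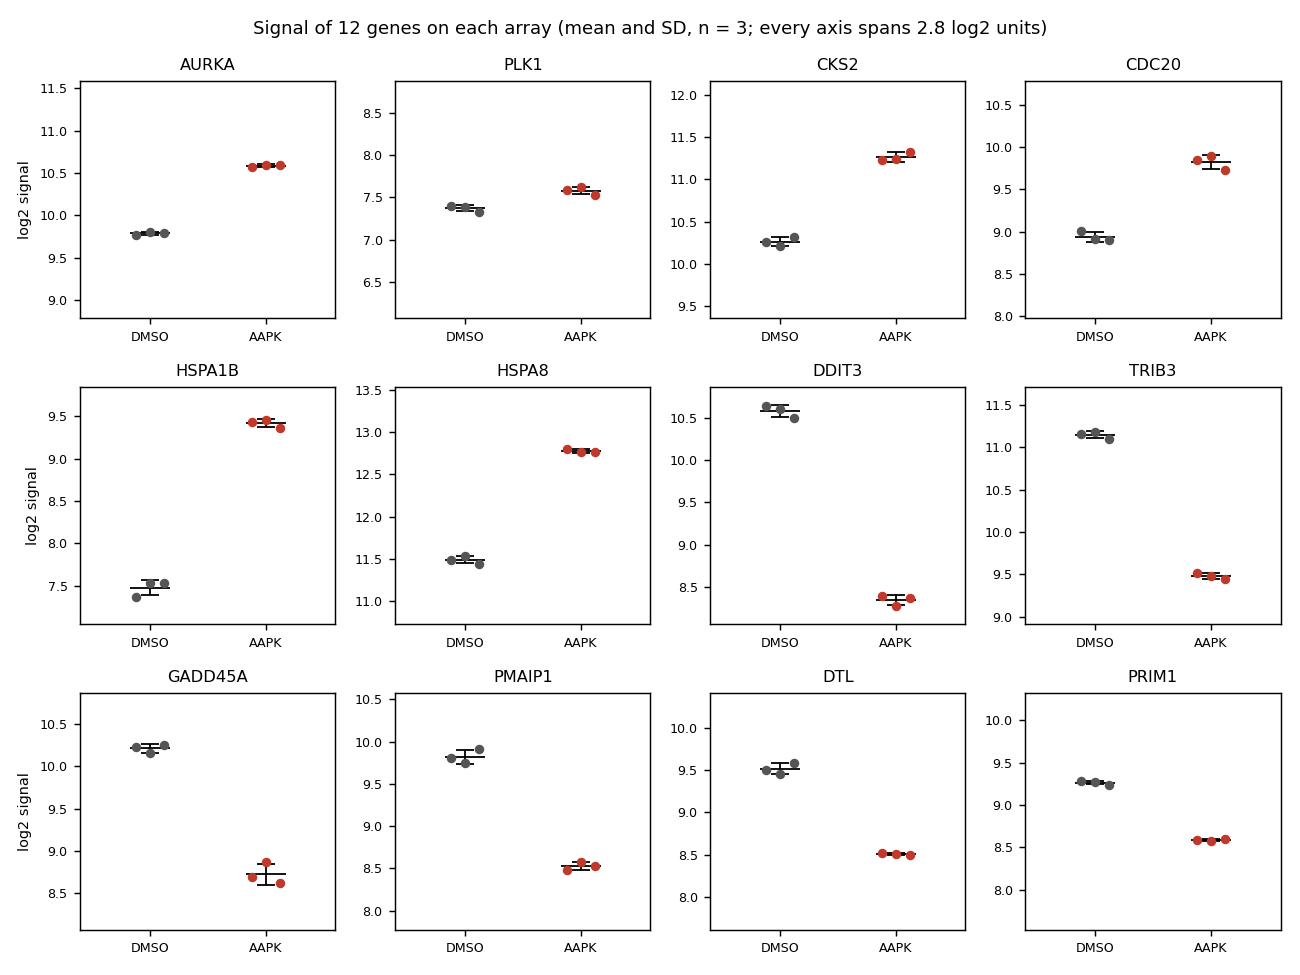
Log2 signal of 12 genes on each array (points), with the mean (horizontal bar) and SD (whiskers, n = 3) for DMSO in grey and AAPK in red; the vertical axes start at different levels and all span the same range. AURKA moved from 9.79 to 10.59, PLK1 from 7.37 to 7.58 and DDIT3 from 10.58 to 8.35.

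Genes of G2 and mitosis rose together. Of 50 measured members, 42 rose and 1 fell (43 and 1 adjusted over the list alone), with a median log2 change of 0.35. CKS2 led them, followed by DLGAP5, a spindle microtubule protein, which rose by 0.92, CDC20, the activator of the anaphase-promoting complex, by 0.88, and CCNB1, cyclin B1, by 0.86. The other 2 CDC20 probe sets were at 0.01 and 0.89. The member that fell was MELK, at -0.15, named after its value was seen. The camera adjusted p was 2.42e-31, and 0.0622 with an estimated correlation.

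Among 45 spindle checkpoint, kinetochore and anaphase-promoting complex genes, 18 rose and 5 fell (21 and 6 adjusted over the list alone). The largest rises were those of CDC20 and of BUB1, a checkpoint kinase, at 0.74. This list shares 7 genes with the G2/M list. Its median was 0.10 (camera adjusted p = 4.39e-05; adjusted p = 0.194 with an estimated correlation), 0.06 with all probe sets fitted and 0.17 on the probe sets with the largest spread.

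Of 46 G1/S and DNA replication genes, 0 rose, 17 fell and 29 did not pass (0 and 21 higher and lower adjusted over the list alone). DTL, a substrate receptor of the CUL4 ubiquitin ligase, was 2.01-fold lower, and PRIM1, a primase subunit, fell by 0.68 on the log2 scale. The median was -0.11 (camera adjusted p = 1.89e-07; adjusted p = 0.1345 with an estimated correlation). Of 28 DNA repair genes, 13 fell and 3 rose (14 and 4 adjusted over the list alone), with a median of -0.12 (camera adjusted p = 1.43e-04; adjusted p = 0.157 with an estimated correlation). RAD51AP1, which assists homologous recombination, fell by 0.60 and the helicase gene BLM by 0.49. Of 41 replication-dependent histone genes 8 fell and 1 rose, led by H4C3 at -0.48 and H2BC5 at 0.39, and the list did not pass (camera adjusted p = 0.377). Histone genes have close copies, so a probe set may read more than 1 of them.

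The amino acid stress response driven by the transcription factor ATF4 was lower. Of 32 measured members 28 fell and 0 rose, with 30 and 0 adjusted over the list alone. The median was -0.59 (camera adjusted p = 2.42e-31; adjusted p = 0.0297 with an estimated correlation). After DDIT3 and TRIB3 came SESN2, a sestrin that senses leucine, which fell by 1.33, and CEBPG, a bZIP partner of ATF4, which fell by 1.32. Chosen after their values were seen, ATF4 itself fell by 0.55 and ASNS, asparagine synthetase, by 0.94.

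Heat shock genes rose. Of 18 measured members 14 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.54 (camera adjusted p = 5.50e-20; adjusted p = 0.0297 with an estimated correlation). After HSPA1B and HSPA8 stood DNAJA1, an HSP40 co-chaperone, at 0.92, and HSPH1, an HSP110, at 0.91. HSPA1B has a near-identical copy, and its value may include that copy. Genes of the unfolded protein response of the endoplasmic reticulum were mixed, 9 higher and 3 lower of 23. MANF, a secreted chaperone-like factor, rose by 0.50 and HERPUD1, a degradation factor, fell by 0.91. The list's median was 0.08 (camera adjusted p = 9.85e-04; adjusted p = 0.157 with an estimated correlation), and it was lost against random lists (adjusted p = 0.134); without AAPK replicate 3 its median was 0.15, and it ran from 0.03 with all probe sets fitted to 0.16 on those with the largest spread.

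Targets of p53 moved both ways, 6 higher and 11 lower of 47 (7 and 12 adjusted over the list alone). GADD45A, SESN2 and PMAIP1, the last encoding the BH3-only protein NOXA, fell by 1.49, 1.33 and 1.29. GDF15, a secreted stress factor, fell by 0.57. Its 4 other probe sets ran from -1.24, on that with the largest spread, to -0.06. CDKN1A and MDM2, chosen after their values were seen, had log2 changes of 0.01 and -0.02 and did not pass. SESN2 is also on the ATF4 list. Among the 46 targets not on that list, 6 were higher and 10 lower, with a median log2 change of -0.01. This split rests on list membership alone. Whether GADD45A, PMAIP1 and GDF15 fell with the ATF4 response was not tested. For all 47 targets the median was -0.01 and the mean -0.12. Camera did not call the list (adjusted p = 0.209), whereas fry, which does not compare it with other genes, did (adjusted p = 9.07e-04). Of 35 apoptosis regulators 4 rose and 6 fell (5 and 8 adjusted over the list alone). PMAIP1 led the falls, TNFSF10, the death ligand TRAIL, fell by 0.41, and BIRC5 (survivin) and CYCS (cytochrome c) rose by 0.51 and 0.42. The other 2 CYCS probe sets were at 0.06 and 0.39. The apoptosis list's median was -0.04 (camera adjusted p = 0.449; fry adjusted p = 0.00289).

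Tubulin genes rose, 8 of 16 against 1 that fell, the same counts adjusted over the list alone. TUBB2A, TUBA1A and TUBA4A rose by 0.67, 0.60 and 0.60, and TUBE1, a centriolar tubulin, fell by 1.13. The median was 0.16 (camera adjusted p = 2.11e-04; adjusted p = 0.0950 with an estimated correlation), and 0.27 or 0.25 with genes under the 25th percentile or the median of signal left out and 0.25 on the probe sets with the largest spread. Tubulins are close paralogs, so signal may be shared between them.

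Several metabolic lists shifted upward by small amounts. Of 42 oxidative phosphorylation genes 12 rose and 0 fell, led by NDUFB3, a complex I subunit, at 0.39 and COX6B1, a complex IV subunit, at 0.34 (median 0.09, camera adjusted p = 1.05e-06; adjusted p = 0.1345 with an estimated correlation). Of 37 ribosome biogenesis and MYC target genes 15 rose and 1 fell (median 0.12, adjusted p = 2.74e-06, and 0.1345 with an estimated correlation), with TFRC, the transferrin receptor, at 0.48 and NOP16 at 0.44 (0.25 for the mean of its probe sets, of which another was at -0.08). The member that fell was CDK4, at -0.41, named after its value was seen. Of 20 cholesterol synthesis genes 9 rose and 0 fell (median 0.15, adjusted p = 5.52e-06, and 0.114 with an estimated correlation), led by IDI1 at 0.56 and NSDHL at 0.33, both enzymes of the pathway. Of 32 hypoxia and glycolysis genes 13 rose and 3 fell (median 0.15, adjusted p = 2.40e-04, and 0.157 with an estimated correlation): NDRG1 rose by 0.89, while the growth factor gene VEGFA fell by 0.78, with -0.44 for the mean of its probe sets. Of 27 NRF2 target genes 8 rose and 2 fell (median 0.04, adjusted p = 0.0200, and 0.1345 with an estimated correlation), with UGDH at 0.47 and GCLM, a glutathione synthesis subunit, at 0.38 (0.25 for the mean of its probe sets). All 5 calls were thus lost with an estimated correlation. Against random lists the oxidative phosphorylation list (adjusted p = 0.168) and the NRF2 list (adjusted p = 0.157) were lost too. With quantile normalisation the oxidative phosphorylation median was 0.04 (adjusted p = 0.00549) and the NRF2 call was lost (adjusted p = 0.0683). The oxidative phosphorylation median was 0.05 with the mean of each gene's probe sets, and the NRF2 median 0.09 with genes under the median signal left out. With all probe sets fitted the cholesterol and hypoxia medians were 0.09 and 0.05.

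Of 25 YAP/TAZ targets 4 fell and 2 rose, with a median of -0.06, or -0.04 with median centring (camera adjusted p = 0.0456; adjusted p = 0.157 with an estimated correlation). That call was also lost against random lists (adjusted p = 0.115), with either signal filter (adjusted p = 0.0915 and 0.0861), with array weights (adjusted p = 0.0607) and without DMSO replicate 3 or AAPK replicate 3 (adjusted p = 0.108 and 0.0589). AJUBA led the falls and GADD45B fell by 0.69, with -0.33 for the mean of its probe sets. The remaining lists did not pass with the preset correlation. Immediate-early transcripts had 6 of 32 lower and 1 higher (adjusted p = 0.0537), with DUSP2, a phosphatase, at 0.63 and KLF4 at -0.60 (-0.39 for the mean of its probe sets). The immediate-early list did pass with quantile normalisation (adjusted p = 0.0275), an intensity trend (adjusted p = 0.0315), either signal filter (adjusted p = 0.0410 and 0.0300) and against random lists (adjusted p = 0.0185), among other alternatives. Lysosome and autophagy genes had 5 of 38 higher and 3 lower (adjusted p = 0.0621), with ULK1, the autophagy kinase, at -0.49 and GLA at 0.34 (0.53 on its probe set with the largest spread). Xenobiotic response genes had 3 of 13 higher and 0 lower (adjusted p = 0.220), with the drug transporter ABCG2 at 0.45 (0.24 for the mean of its probe sets) and NQO1 at 0.33. Of 27 NF-kB genes 2 rose and 2 fell (adjusted p = 0.276), with CXCL2 at -0.39 and IGFBP3 at 0.26; CXCL2 was at -0.60 for the mean of its probe sets and -0.82 on that with the largest spread. Of 38 interferon genes 1 rose and 1 fell (adjusted p = 0.449), IFIH1 at -0.44 (-0.28 for the mean of its probe sets) and IFITM1 at 0.15. The call on IFITM1 was lost whichever array was left out, and with quantile normalisation (0.08, adjusted p = 0.261).

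Few differentiation and cell type markers passed the threshold. Of 23 Wnt target and stem genes 0 rose and 1 fell (list adjusted p = 0.913). The gene that fell was MYB, at -0.24 (adjusted p = 0.00518), a call lost on its probe set with the largest spread, where the change was about as large (-0.25, adjusted p = 0.0549). Of 38 epithelial and enterocyte genes 1 rose and 2 fell (list adjusted p = 0.490). Those that fell were KLF4 and CEACAM1, the latter at -0.22 (adjusted p = 0.00715). The call on CEACAM1 was lost with the mean of its probe sets (-0.05, adjusted p = 0.449) and on that with the largest spread (-0.15, adjusted p = 0.239), and 6 of its 8 other probe sets shared its sign. Among 23 mesenchymal genes none passed limma's threshold (adjusted p = 0.952), nor did any of 13 fibroblast (adjusted p = 0.829) and 12 endothelial markers (adjusted p = 0.377); 4, 1 and 1 of them had an unadjusted p under 0.05. Of 16 blood cell markers 1 rose (list adjusted p = 0.947), SRGN at 0.33. For the mesenchymal and blood lists the median lay below 0 while camera's direction was upward, and for the fibroblast list the median was 0.02 and the mean -0.01.

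**Figure D3:**
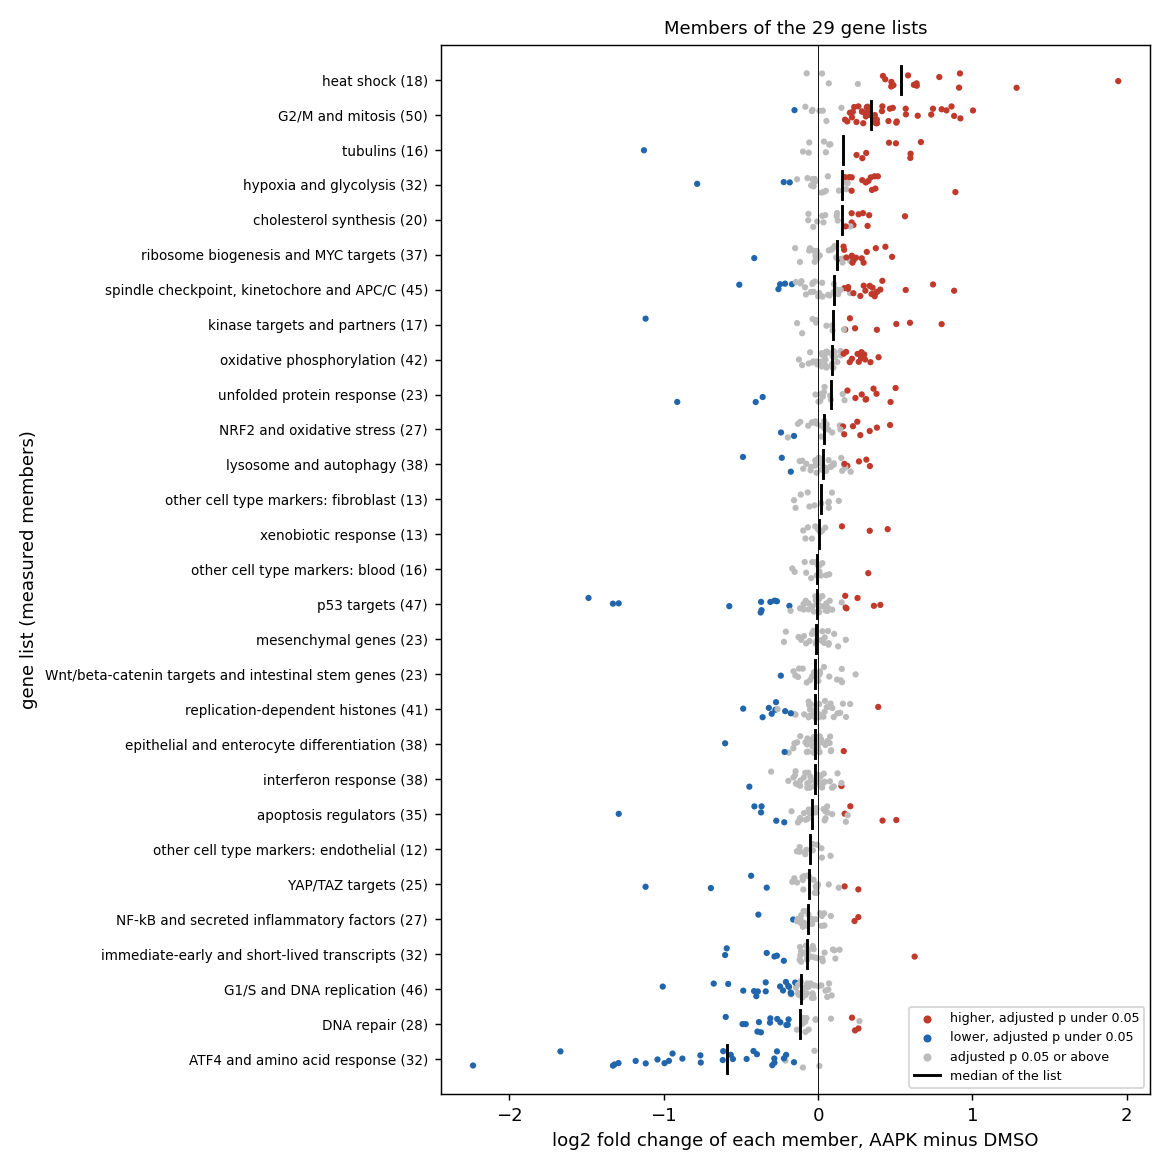
Log2 fold change (horizontal axis, AAPK minus DMSO) of each measured member of the 29 gene lists (rows, ordered by median, with the number of members); red points rose, blue fell and grey did not pass, and black bars are medians. The medians run from -0.59 for the ATF4 list to 0.54 for the heat shock list.

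Of the 29 lists, 15 passed with the preset correlation, 11 upward and 4 downward, and 2 passed with an estimated one, the ATF4 and heat shock lists. Signal differences between the 3′ and 5′ control probe sets of GAPDH and ACTB did not separate the groups (two-sided exact permutation p = 0.6 and 1; 3 arrays against 3 cannot go below 0.1). Of 6 control probe sets for ribosomal RNA, 3 differed: the 5′ and middle sets of the large subunit by 0.56 and 0.51 and the 3′ set of the small one by -0.41 (limma adjusted p = 5.49e-04, 2.52e-04 and 0.00228). The 3′ set of the large subunit was at -0.13 and did not pass (adjusted p = 0.245).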

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

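Signals outside the gene comparison differed between the groups. Among 102 Affymetrix control probe sets, 3 passed limma's threshold, all of them for ribosomal RNA. A probe set for the 5′ part of the large-subunit RNA was higher in AAPK by 0.56 on the log2 scale (9.70 ± 0.12 in DMSO and 10.26 ± 0.07 in AAPK, SD, n = 3; adjusted p = 5.49e-04), and that for its middle part by 0.51 (adjusted p = 2.52e-04). A probe set for the 3′ part of the small-subunit RNA was lower, at -0.41 (adjusted p = 0.00228). The third large-subunit probe set, for its 3′ part, was at -0.13 (adjusted p = 0.245), and the other small-subunit sets were both at -0.06 (adjusted p = 0.633 and 0.699). The mean of the poly-A spike-ins differed by 0.10 and that of the hybridisation spike-ins by -0.02, neither separating the groups (two-sided exact permutation p = 0.8 and 0.9, where 0.1 is the smallest possible).

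Probe sets that name several genes or none also carried a difference. Of 4305 such probe sets, 458 passed the threshold, 291 higher and 167 lower in AAPK. They were not assigned to genes.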

How the results depend on the processing

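For the 62 genes named by the rule, 972 of 985 refitted values kept direction and call at adjusted p 0.05. Another 13 lost only the call and none reversed. AURKA stayed at 0.74 to 0.82 and PLK1 at 0.19 to 0.30, both always called. At 0.01 the PLK1 call was lost (adjusted p = 0.0118, up to 0.0485 in refits). Under the other normalisations, signal filters, summaries per gene and spread models, counts of genes past the threshold ran from 2672 with quantile normalisation (48.6% higher) and 2773 with median centring (61.3% higher) to 3468 with array weights, and from 1923 to 2447 with 1 array left out (1007 to 1307 higher, 892 to 1145 lower). Counts that moved by over 1.5 times were those of an adjusted p of 0.01 (1509 genes, 816 higher and 693 lower), a stricter threshold by construction; of fitting all probe sets (5824 probe sets, 3206 higher and 2618 lower, 55 at least 2-fold), which counts probe sets; and of the probe set with the largest spread (36 genes at least 2-fold), a choice that favours large changes. With an estimated correlation the calls on the G2/M list (median 0.35, adjusted p = 0.0622, range over all alternatives 8.53e-40 to 0.0622), the kinase list (0.0943, p = 0.114, range 6.78e-05 to 0.114; also lost against random lists at p = 0.0503) and the tubulin list (0.16, p = 0.0950, range 3.02e-08 to 0.0950) were lost. The p53 list gained a call in limma with genes under the median signal left out (-0.0043, adjusted p = 0.0434) and with fry (-0.0077, adjusted p = 9.07e-04; range 9.07e-04 to 0.809), as did the apoptosis list with fry (-0.0417, adjusted p = 0.00289; range 0.00289 to 0.638). The cause was not tested, beyond fry's not comparing a list with other genes. Over all 29 lists, 507 of 550 refits kept the main outcome, called or not, while 24 lost a call and 19 gained one. The YAP/TAZ call was lost with genes under the 25th percentile (adjusted p = 0.0915) or the median of signal left out (0.0861), with array weights (0.0607), with an estimated correlation (0.157), against random lists (0.115), without DMSO replicate 3 (0.108) and without AAPK replicate 3 (0.0589); the immediate-early list gained one with quantile normalisation (0.0275), both signal filters (0.0410 and 0.0300), the probe set with the largest spread (0.0351), all probe sets (8.53e-04), an intensity trend (0.0315), array weights (0.0486), fry (0.00268), random lists (0.0185), and without DMSO replicate 2 (0.0219) or AAPK replicate 2 (0.0217). The lysosome list gained one with the block below (0.0482), fry (0.0124) and without AAPK replicate 3 (0.0248), and the xenobiotic and histone lists with fry (0.00293 and 0.00268). The NRF2 call was lost with quantile normalisation (0.0683). Medians of called lists moved by over 1.5 times for oxidative phosphorylation (0.04 to 0.11 over all alternatives), the unfolded protein response (0.03 to 0.16), hypoxia (0.05 to 0.20), cholesterol synthesis (0.09 to 0.20), tubulins (0.15 to 0.27), spindle checkpoint (0.06 to 0.17), kinase targets (0.08 to 0.17), NRF2 (0.04 to 0.09) and YAP/TAZ (-0.08 to -0.03). CEACAM1 and MYB lost calls with other probe sets. IFITM1 lost its call without each of the 6 arrays (adjusted p 0.0547 to 0.145), with quantile normalisation (0.261), the block (0.0947), all probe sets (0.0626) and the probe set with the largest spread (0.102). With the replicate number as a block, 2099 genes passed, 2069 of them among the 2788. Deviations of same-numbered arrays correlated at -0.02, -0.23 and -0.05, so no shared deviation was seen. A pairing without such a shared effect cannot be excluded. Log2 changes under about 0.25 are often missed with 3 arrays per group.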

Other observations

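The tests of probe set choice, proteasome genes, tRNA synthetases, decay targets and gene length were written down before their results were seen; those of signal level, hypoxia genes, S-phase genes, the G2/M to S-phase difference and the splits were chosen after. The further gene groups below were picked after the main results, 11 in all, and their adjusted p-values are over those 11.

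Some further groups of protein folding and turnover genes held mostly genes that rose. Of 27 proteasome subunit genes 24 rose and 0 fell, with a median log2 change of 0.31 (camera adjusted p = 6.16e-21; adjusted p = 0.0734 with an estimated correlation); PSMD1 rose by 0.54 and PSMC2 by 0.51, both chosen after their values were seen. Of 8 subunits of the cytosolic chaperonin, which folds tubulin and actin, 6 rose and 0 fell (median 0.24, adjusted p = 1.95e-06; adjusted p = 0.0734 with an estimated correlation), TCP1 by 0.45 and CCT2 by 0.42, also chosen after their values were seen. Of 71 mitochondrial ribosomal proteins 19 rose and 4 fell (median 0.09, adjusted p = 1.95e-06; adjusted p = 0.394 with an estimated correlation). Among 39 kinesins 9 rose and 0 fell (camera adjusted p = 0.0187, and 0.144 with an estimated correlation). Some kinesin genes that rose are also on the G2/M list, so this group is not independent of it. The kinesin median was -0.01 as deposited and 0.01 with quantile normalisation or median centring. Of 491 ZNF zinc finger genes 51 fell and 11 rose (median -0.04, adjusted p = 0.0130; adjusted p = 0.326 with an estimated correlation). The directions of these medians, kinesins aside, held under both normalisations, but the mitochondrial ribosomal median was 0.05 with quantile normalisation and the ZNF median -0.02 with median centring. Cytosolic ribosomal proteins (4 higher and 3 lower of 71, adjusted p = 0.792), solute carriers (21 and 22 of 369, adjusted p = 0.990) and DNAJ co-chaperones (9 and 5 of 46, adjusted p = 0.160) did not pass.

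Probe sets of the same gene could move in opposite directions. Of 1354 genes with more than 1 probe set past the threshold, 51 had probe sets past it in both directions. For MAT2A a probe set rose by 0.59 while another was at -2.12. HNRNPM, an RNA-binding protein, had 0.46 and -0.57, the splicing factor SRSF10 had 0.37 and -0.45, and RBM15 had 0.32 and -0.37. These genes were chosen after their values were seen, and the transcripts that each probe set reads were not analysed here.

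The fall of the ATF4 list was examined first. Its median lay at percentile 0 of 10000 random lists matched on mean signal, which argues against a drift of the arrays with signal level. The choice of probe set is argued against too, since the 59 other probe sets of its genes had a median of -0.57. Oxygen-poorer control cultures cannot be told apart: the hypoxia list had a median of 0.15, upward, but that call was lost with an estimated correlation and its members went both ways. Of cytosolic tRNA synthetase genes 10 of 19 fell and 2 rose (downward, camera adjusted p = 0.00311; adjusted p = 0.394 with an estimated correlation), and 4 of the 10 are themselves on the ATF4 list. Of 16 mitochondrial ones 0 fell and 1 rose (adjusted p = 0.792); the medians differed by -0.11 (permutation p = 0.119 over genes, which are not independent), which decides nothing. A lower ATF4 activity in treated cells may account for the pattern, as may nutrient or growth differences between the cultures, which were not measured.

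The rise of the G2/M list lay at percentile 100 of matched random lists, so signal level alone is argued against. A general rise of proliferation genes is argued against by the S-phase list, whose median was -0.11 with 0 of 46 genes higher and 17 lower. A larger share of treated cells in G2 or mitosis is a candidate explanation that stays open. The G2/M and S-phase medians differed by 0.46, but both had been seen before they were compared, and both list calls were lost with an estimated correlation (adjusted p = 0.0622 and 0.1345). Cell cycle phase was not measured here, and a change in transcription without a change in phase stays open too.

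The rise of the heat shock list also lay at percentile 100 of matched random lists, against a drift with signal level. If it belonged to a wider response to damaged protein, proteasome genes would rise by at least 0.2, and their median was 0.31. Such a response thus remains a hypothesis. The proteasome call was lost with an estimated correlation, and growth-related control of the same genes stays open. The heat shock genes HSPA6 and DNAJB1, chosen after their values were seen, were at 0.03 and -0.07 and did not pass, whereas 14 of 18 members rose.

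Genes lower in AAPK were tested for 2 shared properties. The log2 change did not fall with gene length (Spearman rho = 0.0025 and Pearson r = 0.0011 across 18111 genes, which are not independent replicates; permutation p = 0.720). Known targets of nonsense-mediated decay had a median of -0.012 over 11 genes, 1 higher and 1 lower, and of 0.0075 with median centring. The 11 include host genes of small nucleolar RNAs and genes of decay factors. Both medians lay above -0.2, a cutoff that was written down beforehand but chosen freely. The host genes SNHG7, SNHG8, ZFAS1 and EPB41L4A-AS1 were at -0.10, -0.15, -0.20 and -0.12 and SNHG12 at 0.02, while the decay factors went both ways. The median therefore mixes unlike genes. Strongly lower genes such as DDIT3 (-2.23) and GADD45A (-1.49) are not among the 11, so the group cannot speak for them. Other targets of this decay were not tested as a group, so faster decay of some transcripts stays open.

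As for chance in how arrays were grouped, 1 of the 10 splits of the 6 arrays, the real one, gave 2788 genes in limma, and the highest of the others gave 0, with at most 872 genes at an unadjusted p under 0.05. With 10 splits no share under 0.05 can be reached.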
